A study of Homo sapiens with 4 samples.

How the data were processed

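RNA-seq was carried out on 4 libraries of SF8628 cells, 2 untreated and 2 given DMKG for 48 h. Groups and replicate numbers were taken from the sample titles. The deposited table holds FPKM values (values scaled to gene length and library size) for 28256 genes, which the authors made with HOMER's analyzeRepeats program on hg38, per the file headers. Exon reads were counted on either strand, 1 transcript was kept per gene, and no scaling between samples was applied, per the file headers. HISAT2, HOMER and DESeq2 are named in the submitters' processing notes, with no version and no role. Per the labels' protocols, total RNA was isolated with TRIzol and libraries followed standard Illumina protocols. The strandedness of the libraries and the read length are not given in the sources used here. Since reads were counted on either strand, a gene cannot be told apart from an antisense or overlapping partner. HOMER also lists how many loci a gene model has: 2296 rows have more than 1, and 570 rows are placed on alternate or unplaced contigs. Coordinates are those of the table, counted from 1. The mitochondrial chromosome has 1 row, so the list of mitochondrially encoded transcripts had 0 matches.

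The depth was recovered from the values. In each sample, FPKM multiplied by gene length gave whole multiples of a single step for 100% of the low values tested (up to 20 reads, within 0.1 of a read, 2471 to 2651 values per sample). These steps correspond to 33135340, 33703251, 35837846 and 28360417 reads for untreated replicates 1 and 2 and DMKG replicates 1 and 2. Recovered reads served for low values, for a voom alternative and for a check that the 2 samples of a group are not copies of 1 library (chi-square over degrees of freedom of 28.1 within the untreated and 10.6 within the DMKG group). Counting intervals are exact 95% intervals and cover counting error only.

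Values were analysed as log2(FPKM + 1). Genes had to be at least 200 nt long and to have a mean of at least 1 FPKM over the 4 samples, which left 12327 genes. DMKG was compared with untreated cells with limma 3.58.1 in R 4.3.3, using a mean-variance trend, no replicate block and a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of low genes; "n-fold" values in the text are ratios of group means in FPKM. With 2 samples per group, an exact permutation test of a single value cannot give a p below 0.333, so the tests rest on the spread pooled across genes. No split of the samples into other groups was tested, for the same reason.

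Before the data were examined, 45 gene lists with 1241 entries were fixed from general knowledge, of which 1225 matched a gene in the table and 977 were tested. The 42 lists with at least 5 tested genes were compared with all other genes by camera with a preset correlation of 0.01, and again with an estimated correlation. The fry test, which sets a list against no change rather than against other genes, was run as an alternative. With the preset correlation 9 lists were called up and 5 down, and with the estimated correlation 0. Genes named in the text follow a rule fixed at the same time. It takes the 12 largest changes per direction among called genes whose samples do not overlap and whose higher group mean is at least 5 FPKM, up to 4 called genes per list, and a fixed set of cell cycle, chromatin and 2-oxoglutarate genes with ACTB and GAPDH. Genes named outside this rule are said to be so.

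The same functions were tested on simulated data for the comparison of DMKG with untreated cells, with 200 changed genes among 12312 genes run. Counts were drawn independently for each gene from the real means and library sizes. A single spread value was used per group, and no length or GC trend was put in. Of 50 genes changed 1.3-fold, 26.0% were recovered, of 50 changed 1.5-fold 44.0%, of 50 changed 2-fold 100%, and of 50 changed 4-fold 94.0%. Of 12116 unchanged genes 11 were called, 7.69% of all calls. Of 40 lists of unchanged genes camera called 0, and it called a list in which 20 of 30 genes rose. Since the simulated genes varied independently, these list results do not cover correlation between genes in the real data.

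Alternatives tried were the pseudocount (0.1 and 5), the filter on low values (none, or a mean of at least 5 FPKM), median centring, quantile normalization, rescaling to TPM, no trend, a robust fit, short features kept, the replicate block, each sample left out in turn, voom on recovered reads, and a loess trend on gene length removed (span 0.3). A fit to genes with 1 locus on the primary chromosomes, a GC trend removed, and the length trend removed with the replicate block were chosen after seeing the data. GC content of the GENCODE v29 gene models was available for 98.5% of tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The study's epigenetic and proliferation assays were not analysed here.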

Results

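RNA-seq profiles were collected from SF8628, an established cell line from a diffuse intrinsic pontine glioma (DIPG), a childhood tumour of the brainstem. The cells were left untreated or were given dimethyl alpha-ketoglutarate (DMKG) for 48 h. DMKG is a cell-permeable methyl ester of alpha-ketoglutarate (2-oxoglutarate), the citric acid cycle intermediate that is also a co-substrate of the histone and DNA demethylases and of the HIF prolyl hydroxylases. There were 4 libraries, 2 untreated and 2 treated. The sample titles and the treatment protocol gave the dose as 10 mM, whereas the treatment field gave 10 nM. The series title states that the compound inhibited proliferation and altered epigenetic and transcriptional networks, and the comparison asks which transcripts differed between treated and untreated cells.

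Library totals recovered from the FPKM values were 33135340 and 33703251 reads for the untreated samples and 35837846 and 28360417 for the treated ones. Summed over all listed gene models, recovered reads came to 28237006, 27983951, 29744998 and 23343725, where overlapping gene models can count a read more than once. The 2 untreated samples correlated at r = 0.991 and the 2 treated samples at r = 0.994 across the 12327 tested genes, and pairs from different groups at r = 0.959 to 0.971. The median absolute log2 difference was 0.15 between the untreated samples and 0.10 between the treated ones, against 0.23 to 0.29 between groups. The labels do not say whether the 2 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

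Treatment with DMKG was accompanied by a coordinated rise of hypoxia-inducible and glycolytic genes and a fall of mitotic genes. CA9, the hypoxia-inducible carbonic anhydrase, went from 4 reads in the untreated samples together to 5931 in the treated ones. NDRG1, a stress and hypoxia response gene, rose 14.5-fold, from 35.1 ± 1.52 to 510 ± 7.13 FPKM (SD, n = 2 per group). CENPE, which encodes the kinetochore motor protein CENP-E, fell from 17.6 ± 2.85 to 6.06 ± 0.811 FPKM, 2.91-fold lower. In the limma test with Benjamini-Hochberg adjustment, 1326 genes were higher and 2450 lower with DMKG, and 194 and 90 of these differed by at least 1 in log2(FPKM + 1). The median log2 fold change over all tested genes was −0.09. The share of lower genes among the calls depended on the scaling between samples: it was 64.9% as deposited, 45.9% with samples centred on their medians, 51.2% with quantile normalization, 49.0% with the gene length trend removed and 48.6% with the GC trend removed. None of the 3776 genes called as deposited was called in the opposite direction under any of these settings.

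**Figure D1:**
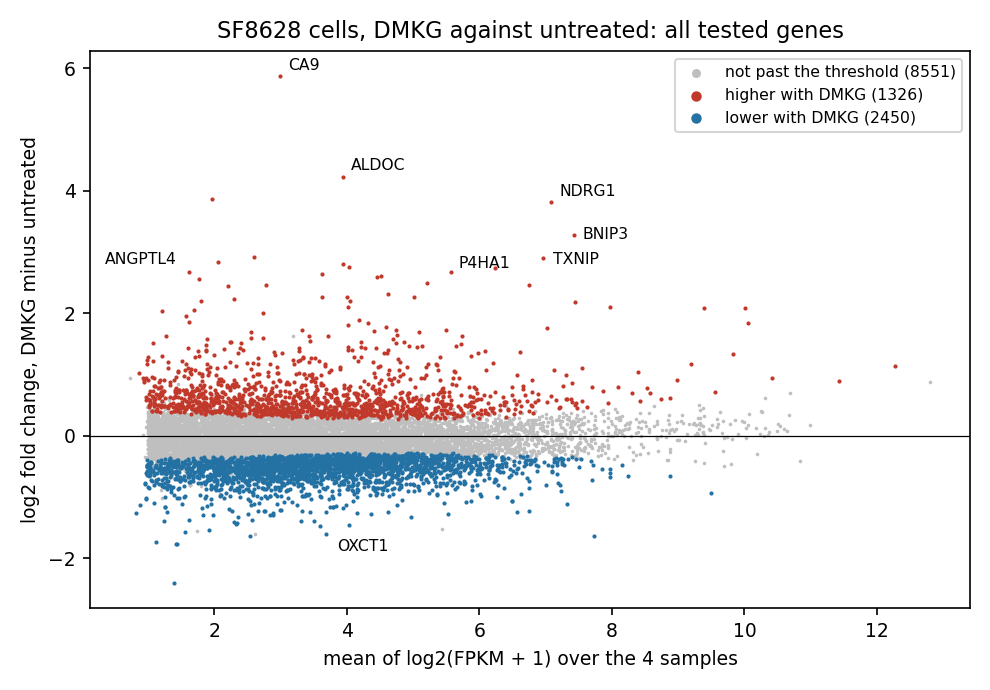
Each point is a tested gene, with the mean of log2(FPKM + 1) over the 4 samples on the x axis and the log2 fold change, DMKG minus untreated, on the y axis. Red points (1326) were higher and blue points (2450) lower with DMKG at an adjusted p under 0.05, grey points (8551) did not pass, and CA9 stands highest with a log2 fold change of 5.88.

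All 35 tested genes of the hypoxia and HIF target list rose, with a median log2 fold change of 1.89 and the same count adjusted over the list alone. The mitophagy receptor gene BNIP3 rose from 54.4 ± 3.09 to 539 ± 0.356 FPKM, 9.91-fold. VEGFA, which encodes the angiogenic growth factor, rose 6.71-fold, from 8.25 ± 0.455 to 55.3 ± 3.59 FPKM (log2 fold change 2.61, SE 0.0978, limma adjusted p = 8.51e-06). TMEM45A rose 8.18-fold. The untreated level of CA9 (chromosome 9, positions 35673928 to 35681157 in hg38) rested on 4 reads in replicate 1 and 0 in replicate 2. Its ratio of reads scaled to library size was 1544, with an exact 95% counting interval of 603 to 5668. Camera ranked the list first (adjusted p = 1.24e-41), and the adjusted p = 0.268 with an estimated correlation, which has only 2 residual degrees of freedom here. No list reached 0.05 in that form of the test. The transcript of the HIF-1 alpha subunit itself, HIF1A, was at 40.7 ± 5.06 and 31.4 ± 1.90 FPKM (log2 fold change −0.36, limma adjusted p = 0.0450); HIF1A was not on a list and was looked up after the list result was seen. That call was lost in several settings, among them median centring (adjusted p = 0.117), quantile normalization (0.113), the GC trend removed (0.286) and each of DMKG replicates 1 (0.316) and 2 (0.103) or untreated replicate 2 (0.0861) left out.

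Of 22 tested glycolysis genes, 19 rose and 2 fell, and 20 rose and 2 fell when adjusted over the list alone (median log2 fold change 1.46). The aldolase gene ALDOC rose 25.7-fold, from 2.56 ± 0.547 to 65.7 ± 5.22 FPKM. PFKFB4, which encodes a regulator of phosphofructokinase, rose 7.80-fold, ENO2 (enolase 2) 6.87-fold and SLC16A3 (the lactate exporter MCT4) 5.59-fold. The 2 that fell, named after their values were seen, were PFKM at −0.43 and SLC16A1 at −0.39 on the log2 scale; both calls were lost without DMKG replicate 1 (adjusted p = 0.129 and 0.265) or 2 (0.103 and 0.0808). PKM, also named after its value was seen, was at 0.63 (adjusted p = 0.0506). Of these genes 6 are also on the hypoxia list, and 13 of the other 16 rose. The hypoxia list need not hold every HIF target, so this count does not separate a glycolytic from a hypoxia response. The same limit holds for such counts given below for the collagen, extracellular matrix, senescence-associated secretory and demethylase lists. Camera gave an adjusted p = 1.33e-17, and adjusted p = 0.482 with an estimated correlation.

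Of 16 collagen hydroxylation genes 10 rose and 0 fell, also when adjusted over the list alone (median log2 fold change 0.47), and 5 were higher without DMKG replicate 1. P4HA1, a subunit of collagen prolyl 4-hydroxylase, rose 6.69-fold, from 17.8 ± 1.02 to 119 ± 4.90 FPKM, and the lysyl hydroxylase gene PLOD2 rose 4.58-fold. P4HA1 and P4HA2 are on the hypoxia list too, and 8 of the other 14 rose. The list had a camera adjusted p = 1.52e-06, and adjusted p = 0.570 with an estimated correlation. In the extracellular matrix list, 11 of 32 genes rose and 3 fell (12 and 6 adjusted over the list alone). LOXL2, a collagen cross-linking oxidase, rose 5.41-fold and COL5A1 4.66-fold. Without LOX and LOXL2, which are among the hypoxia targets too, 9 of 30 rose. This list's median was 0.06 (camera adjusted p = 0.0178, and adjusted p = 0.482 with an estimated correlation); the call was lost under quantile normalization (adjusted p = 0.0735) and with the GC trend removed (adjusted p = 0.130), and without untreated replicate 1 the median was −0.03. Without DMKG replicate 1 there were 6 genes higher, with the length trend removed 18, and without untreated replicate 1 there were 8 lower.

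Among genes of the senescence-associated secretory list, 11 of 20 rose and 3 fell (11 and 4 adjusted over the list alone; median 0.61). STC1 rose 5.40-fold and IGFBP3 4.32-fold, whereas GDF15, a stress-induced cytokine, fell from 5.48 ± 0.561 to 1.23 ± 0.148 FPKM. VEGFA is shared with the hypoxia list, and 10 of the remaining 19 rose. Camera gave an adjusted p = 4.01e-04, and adjusted p = 0.482 with an estimated correlation.

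NRF2 targets, the antioxidant and detoxification genes, rose in 18 of 28 cases with none lower (21 adjusted over the list alone; median log2 fold change 0.66). The aldo-keto reductase AKR1C1 rose 7.52-fold, from 3.97 ± 0.627 to 29.9 ± 1.11 FPKM, and its near-identical neighbours AKR1C2 and AKR1C3 rose 4.78-fold and 3.81-fold, so reads could be split among them. HMOX1 (heme oxygenase 1) rose 3.27-fold. Camera gave an adjusted p = 7.93e-14, and adjusted p = 0.482 with an estimated correlation.

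**Figure D2:**
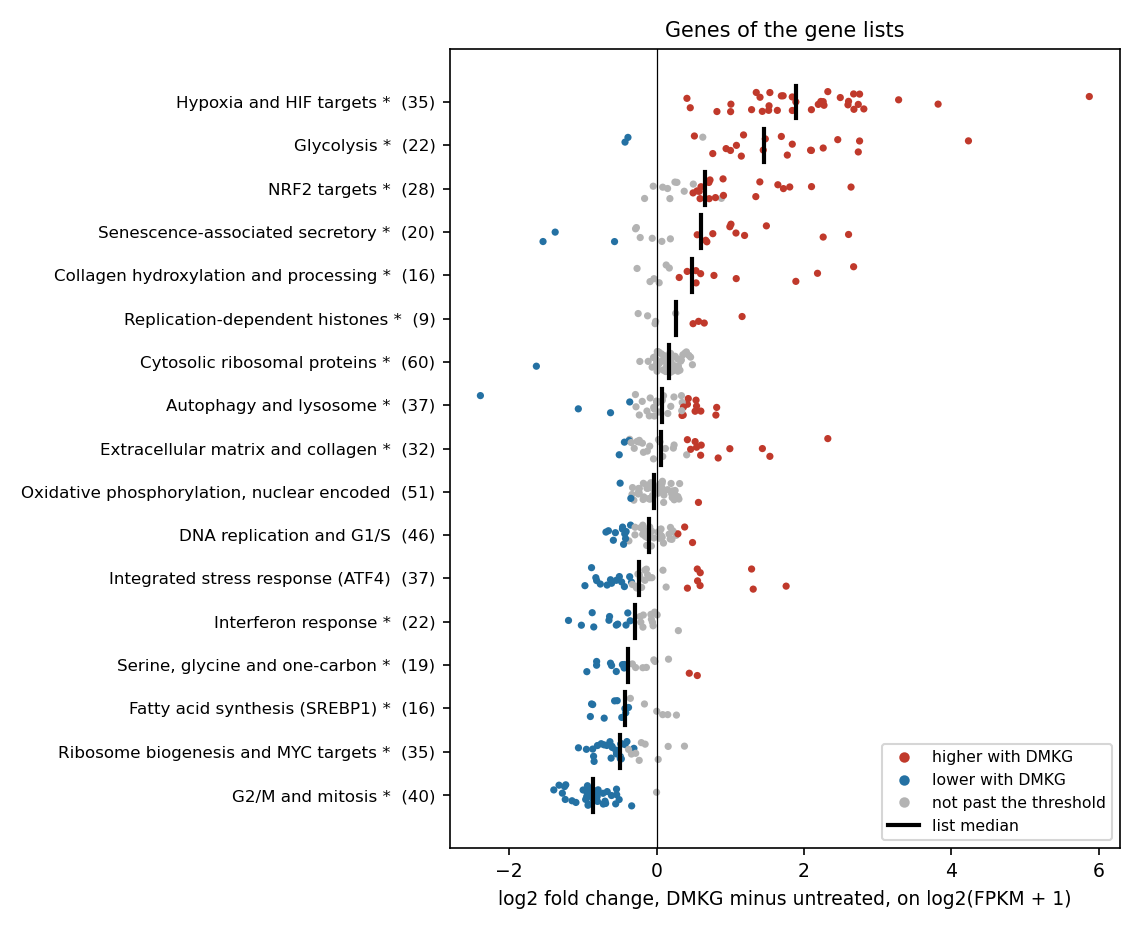
Each point is a tested gene of a list (number tested in brackets), placed by its log2 fold change, DMKG minus untreated, with red for higher, blue for lower, grey for not past the threshold and a black bar for the list median; an asterisk marks lists called by camera with its preset correlation. Hypoxia and HIF targets lie farthest right (median 1.89) and G2/M genes farthest left (median −0.87), while the DNA replication median is −0.10.

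Mitotic genes fell together. Of 40 tested G2/M and mitosis genes, 39 fell, also when adjusted over the list alone, and the median log2 fold change was −0.87. The centromere gene CENPF went from 48.9 ± 8.41 to 18.8 ± 0.870 FPKM and the centromeric histone gene CENPA from 31.2 ± 2.15 to 12.2 ± 0.0368 FPKM. KIF23, which encodes a kinesin of cytokinesis, was 2.51-fold lower. The proliferation marker MKI67 fell from 29.3 ± 3.81 to 14.8 ± 1.03 FPKM (log2 fold change −0.93, SE 0.115, limma adjusted p = 0.00162). PTTG1, named after its value was seen, was the exception, at 145 ± 25.1 and 144 ± 9.90 FPKM. Camera gave an adjusted p = 5.46e-18, and adjusted p = 0.482 with an estimated correlation.

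Of 46 DNA replication and G1/S genes 3 rose, 11 fell and 32 did not pass (3 and 11 adjusted over the list alone), with a median of −0.10 and a camera adjusted p = 0.621. The counts were 5 higher and 7 lower with median centring, 7 and 5 with the GC trend removed, 6 and 13 without untreated replicate 1, 1 and 4 without DMKG replicate 1, and 0 and 7 without DMKG replicate 2. RFC3, a subunit of the replication clamp loader, was 1.66-fold lower and the helicase cofactor gene CDC45 1.63-fold lower. E2F1, named after its value was seen, was highest at 0.49 on the log2 scale, a call lost without DMKG replicate 2 (adjusted p = 0.0574). Among replication-dependent histone genes, 4 of 9 rose and 0 fell (the same adjusted over the list alone; median 0.26, or 0.11 without untreated replicate 2), and 2 were higher without DMKG replicate 1, without DMKG replicate 2 (1 lower) and with voom. The linker histone gene HIST1H1C rose 2.27-fold. The histone list had a camera adjusted p = 0.0279, and adjusted p = 0.606 with an estimated correlation; its median was −0.03 without a filter on low values (adjusted p = 0.437), and the call was lost without DMKG replicate 1 (adjusted p = 0.0693), with voom (0.0505) and with the length trend removed (0.113).

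Of the 10 tested CDK inhibitor genes, 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.648). CDKN1A, which encodes p21, rose from 23.7 ± 1.77 to 52.9 ± 3.33 FPKM (log2 fold change 1.12, SE 0.101, limma adjusted p = 4.51e-04), and CDKN1B, which encodes p27, fell from 19.2 ± 0.711 to 11.2 ± 0.284 FPKM. CDKN2A was at 19.7 ± 2.47 and 19.5 ± 3.33 FPKM. Other p53 targets did not follow CDKN1A: it was the only gene of 26 that rose, and 6 fell (also adjusted over the list alone), among them GDF15, AEN and SESN2; the camera adjusted p was 0.631. CCND1 (cyclin D1) was at 76.1 ± 0.671 and 72.3 ± 7.06 FPKM.

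**Figure D3:**
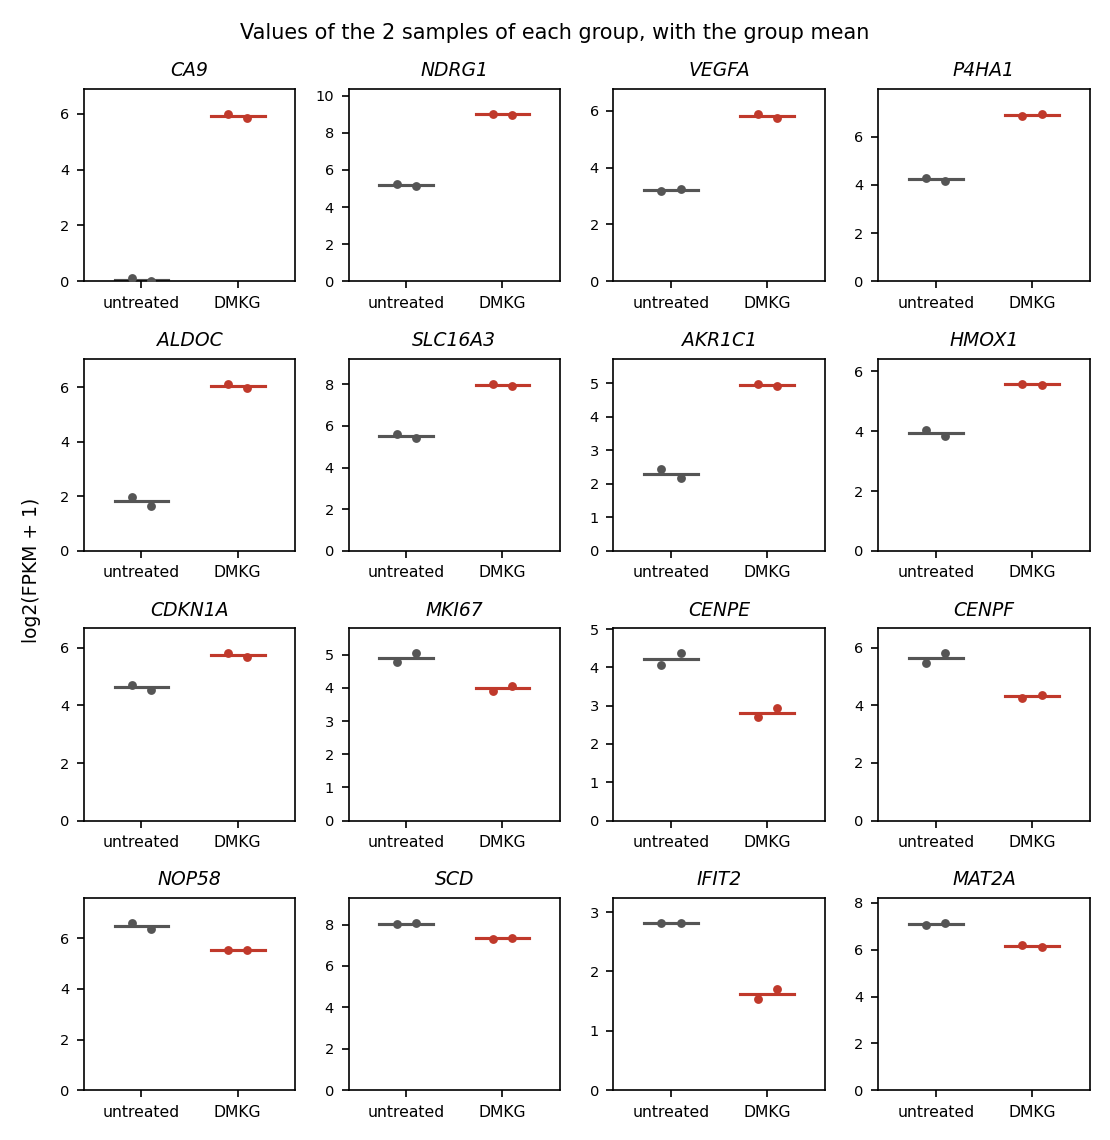
Each panel shows log2(FPKM + 1) of one gene in the 2 untreated (grey) and 2 DMKG (red) samples, with a line at the group mean. Both treated samples lie above both untreated ones for the genes from CA9 to CDKN1A and below them for the genes from MKI67 to MAT2A.

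Ribosome biogenesis and MYC target genes fell in 25 of 35 cases with 0 higher (29 lower and 1 higher adjusted over the list alone; median −0.49). The nucleolar helicase gene DDX21 was 2.12-fold lower and the snoRNP gene NOP58 fell from 89.2 ± 10.0 to 45.4 ± 0.627 FPKM. MYC itself was at 11.9 ± 0.205 and 12.1 ± 0.572 FPKM. The camera adjusted p was 2.32e-07, and adjusted p = 0.482 with an estimated correlation. For the 60 cytosolic ribosomal protein genes, camera gave an upward call (adjusted p = 0.00482, and adjusted p = 0.75 with an estimated correlation), with a median of 0.17 that became −0.05 under quantile normalization. No member was called higher and 1, RPS18, was called lower, also adjusted over the list alone; it is listed at 6 loci. These counts depended on the setting: 5 were higher and 14 lower under quantile normalization, 5 were higher after rescaling to TPM, 10 with the length trend removed and 24 without untreated replicate 1. That upward call was lost under quantile normalization (adjusted p = 0.323), without untreated replicate 2 (adjusted p = 0.600), without DMKG replicate 1 (0.378) and without DMKG replicate 2 (0.0518).

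In the fatty acid synthesis list, 10 of 16 genes fell and 0 rose (11 and 1 adjusted over the list alone; median −0.42). The elongase gene ELOVL6 was 1.94-fold lower, and SREBF1, which encodes the transcription factor SREBP1, was 1.90-fold lower. Camera gave an adjusted p = 0.0133, and adjusted p = 0.482 with an estimated correlation; 3 genes were lower without DMKG replicate 1 and 4 without DMKG replicate 2. In the serine, glycine and one-carbon list, 9 of 19 fell and 2 rose (11 and 2 adjusted over the list alone; median −0.39). MAT2A, which makes S-adenosylmethionine, went from 136 ± 5.75 to 70.3 ± 1.98 FPKM and MTHFD1 was 1.81-fold lower. The 2 that rose, PHGDH at 0.55 and MTHFD1L at 0.44 on the log2 scale, were named after their values were seen and were not called without DMKG replicate 1 (adjusted p = 0.102 and 0.107). This list had a camera adjusted p = 0.0397, and adjusted p = 0.482 with an estimated correlation. Its call was lost without untreated replicate 1 (adjusted p = 0.0506), without DMKG replicate 1 (0.114) or 2 (0.0734), and with a minimum mean of 5 FPKM (0.118). The cholesterol synthesis list had 9 of 24 genes lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.165).

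Interferon response genes fell in 11 of 22 cases with 0 higher, also adjusted over the list alone (median −0.29). The interferon-induced gene IFIT2 went from 6.04 ± 0.00354 to 2.08 ± 0.252 FPKM and OASL was 2.65-fold lower. Camera gave an adjusted p = 0.00676, and adjusted p = 0.482 with an estimated correlation; with a minimum mean of 5 FPKM the adjusted p was 0.229 and 4 genes were lower, and 7 were lower without DMKG replicate 1. The autophagy and lysosome list had 11 of 37 genes higher and 4 lower (13 and 5 adjusted over the list alone; median 0.08). The cathepsin gene CTSL rose 1.76-fold and GPNMB fell from 130 ± 0.942 to 61.6 ± 0.277 FPKM. Its camera adjusted p was 0.0266, and adjusted p = 0.616 with an estimated correlation, and the call was lost whichever sample was left out (0.170 without untreated replicate 1, 0.221 without untreated replicate 2, 0.319 without DMKG replicate 1 and 0.273 without DMKG replicate 2). Without DMKG replicate 2 there were 6 genes higher, and with the length trend removed 17.

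A list of 2-oxoglutarate-dependent enzymes, called demethylase genes here for short, was examined. Beside histone and DNA demethylase genes it holds ALKBH genes and FTO, whose products act on RNA or damaged DNA. It also holds the hydroxylase genes HIF1AN, RIOX1, RIOX2 and JMJD6, so its counts do not describe chromatin demethylases alone. Of 29 tested demethylase genes, 7 rose and 3 fell (10 and 8 adjusted over the list alone; 7 and 7 without untreated replicate 1, 5 and 0 without DMKG replicate 1, 4 and 1 without DMKG replicate 2), with a median of 0.03 and an upward camera direction (adjusted p = 0.189). The median became −0.02 when values were rescaled to TPM, −0.03 with a minimum mean of 5 FPKM and −0.08 without untreated replicate 1. Without untreated replicate 2 camera called the list upward (0.0355) although its median was −0.03. KDM3A, a histone H3 lysine 9 demethylase, rose 3.07-fold, from 9.93 ± 0.885 to 30.5 ± 1.61 FPKM, and KDM4B 2.15-fold. KDM3A, KDM4B and KDM4C are also on the hypoxia list, and without them 4 of 26 rose and 3 fell. ALKBH5, an RNA demethylase, rose 1.85-fold. TET2 was at 2.95 ± 0.725 and 2.36 ± 0.339 FPKM and TET3 at 3.06 ± 0.634 and 2.07 ± 0.0707 FPKM; neither passed, but without untreated replicate 1 both were called lower (adjusted p = 0.0196 and 0.00160), as was TET3 with voom (0.0276). The histone H3 lysine 27 demethylase genes KDM6A (5.76 ± 0.740 and 5.91 ± 0.233 FPKM) and KDM6B did not pass, though with the length trend removed KDM6B was called higher (adjusted p = 0.0230). TET1 lay below the filter, at 0.346 and 0.724 FPKM untreated and 0.457 and 0.669 FPKM treated.

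In the polycomb and DNA methylation list, 4 of 26 genes fell and 1 rose, also adjusted over the list alone (median −0.21, camera adjusted p = 0.388). EZH2, the histone H3 lysine 27 methyltransferase, fell from 42.5 ± 0.610 to 31.1 ± 0.349 FPKM, EZH1 rose from 13.8 ± 0.192 to 20.4 ± 0.823 FPKM and DNMT3B was 1.79-fold lower. The EZH2 call was lost without DMKG replicate 1 (adjusted p = 0.125) or 2 (0.0810). DNMT1 fell from 39.5 ± 1.91 to 30.4 ± 2.29 FPKM (adjusted p = 0.0282), a call lost under median centring (0.0750) and quantile normalization (0.0643), with no filter on low values (0.0584), and without DMKG replicate 1 (0.332) or 2 (0.0835). H3F3A, one of the genes for histone H3.3, was at 70.6 ± 3.34 and 63.3 ± 4.49 FPKM.

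Enzymes and transporters of 2-oxoglutarate metabolism were on 2 lists. In the citric acid cycle list, 2 of 25 rose and 7 fell (2 and 8 adjusted over the list alone; median −0.18, camera adjusted p = 0.289). SUCLG2, a succinyl-CoA ligase subunit, was 1.83-fold lower. IDH1 was 1.41-fold lower (adjusted p = 0.00809), a call lost without DMKG replicate 1 (0.107) or 2 (0.0706). IDH2 was at 12.6 ± 0.137 and 15.1 ± 0.579 FPKM (adjusted p = 0.0777), and was called higher under median centring (0.0340), quantile normalization (0.0285) and with the length trend removed (0.0312). OGDH was at 49.4 ± 0.0332 and 51.6 ± 0.907 FPKM, with an adjusted p = 0.0416 once the length trend was removed. In the glutamine and glutamate list, 1 of 24 rose and 8 fell, also adjusted over the list alone (median −0.17, camera adjusted p = 0.228), and the glutamine transporter gene SLC38A1 was 2.26-fold lower. Of 51 nuclear genes of oxidative phosphorylation, 1 rose and 2 fell (1 and 1 adjusted over the list alone). That list had a median of −0.03, a mean of −0.01 and an upward camera direction (adjusted p = 0.508); without untreated replicate 1 the median was 0.12 and camera called it upward (0.0356).

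Stress lists were mixed. For ATF4 targets of the integrated stress response, 8 of 37 rose and 14 fell (8 and 16 adjusted over the list alone; median −0.23, camera adjusted p = 0.381). DDIT4 rose 3.41-fold and ATF5 was 2.17-fold lower. Of 18 heat shock genes 5 fell and 0 rose, also adjusted over the list alone. The heat shock median was −0.31 and the camera adjusted p = 0.0502, with HSPH1 1.78-fold lower, and the list was called lower in several other settings, quantile normalization among them (adjusted p = 3.84e-04). The unfolded protein response list had 1 of 23 genes higher and 5 lower, also adjusted over the list alone (adjusted p = 0.688).

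Outside the lists, TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose 7.65-fold, from 44.3 ± 0.450 to 339 ± 3.02 FPKM, PPFIA4 12.9-fold and DEPP1 18.2-fold. MIR210HG, the host transcript of the hypoxia-inducible microRNA miR-210, had 4 reads in the untreated samples and 2079 in the treated ones. It is listed at 2 loci and its row is placed on an alternate contig, so its value is uncertain. OXCT1, which encodes the rate-limiting enzyme of ketone body use, fell from 21.6 ± 0.661 to 6.41 ± 0.240 FPKM (log2 fold change −1.61, SE 0.0947, limma adjusted p = 6.38e-05). PDE1C, a cyclic nucleotide phosphodiesterase gene, was 4.05-fold lower, SYT13 3.54-fold, SGO2 3.06-fold and FAM13B 2.94-fold. PIK3R3 was 3.49-fold lower; it overlaps a read-through transcript that can count the same reads. RPS18 and NAP1L4 were also among the 12 largest falls, but each is listed at more than 1 locus and its row is placed on an alternate contig, so their values are uncertain. NAP1L4 differed widely between the treated samples (10.9 ± 9.14 FPKM) and had an adjusted p = 0.0488, a call lost in most settings with all samples (0.0759 with median centring, 0.0789 with quantile normalization and 0.299 with a robust fit, for example).

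Reference genes were not uniformly stable. Of 26 commonly used reference genes, 5 rose and 2 fell, also adjusted over the list alone, and the median of 0.01 became −0.02 under quantile normalization and −0.05 when rescaled to TPM (camera adjusted p = 0.149); without untreated replicate 1 it was 0.12 and the list was called (0.0274). PGK1 rose 4.32-fold. GAPDH rose from 3327 ± 449 to 7364 ± 560 FPKM (adjusted p = 0.0369), a difference that was 0 under quantile normalization because GAPDH held the same rank in every sample, and whose call was lost with no filter on low values (0.356) and without DMKG replicate 1 (0.485) or 2 (0.407). ACTB was at 2122 ± 283 and 1601 ± 77.5 FPKM (adjusted p = 0.230); it was called lower under quantile normalization (2.89e-05), after rescaling to TPM (0.0107), with no trend (0.0475), with voom (0.0390) and with the length trend removed (0.00999).

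Markers of other cell types were tested as lists. Neither the astrocyte list (0 of 10 higher, 2 lower, or 4 lower adjusted over the list alone; adjusted p = 0.381) nor the neuron list (1 of 6 higher and 1 lower, adjusted p = 0.604) passed camera, although the neuron list did without untreated replicate 1 (0.0309). No call was made for the endothelial and mural (4 of 10 higher, 3 lower, or 4 lower over the list alone; 0.621), epithelial (1 of 6 higher, 0 lower; 0.189) and fibroblast lists (4 of 18 higher, 4 lower, or 5 lower over the list alone; 0.218). The neuron and endothelial medians were −0.05 and −0.12, while their means were 0.31 and 0.03 and camera pointed up. The 1 higher gene of the neuron list was ENO2 (log2 fold change 2.74), which is also on the hypoxia and glycolysis lists. The neuron list thus gave no rise separate from the hypoxia list. The oligodendrocyte list had 3 tested genes, 1 of them higher, and the microglia and immune list 2, 1 of them higher, too few for a list test. Gene length was related to the fold change across genes (Spearman's rho −0.194). It was related more strongly to the difference between the 2 untreated samples (−0.553) and between the 2 treated samples (−0.427), replicate 1 minus 2. GC content had a rho of 0.366 with the fold change, and genes are not independent replicates. The counts of 35 hypoxia targets higher and 39 mitotic genes lower were the same with either trend removed.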

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

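Features shorter than 200 nt, mostly microRNA precursors and small nucleolar RNAs, were kept out of the comparison, since a library of total RNA fragments measures them poorly and reads of a host gene cannot be told apart from theirs. Signal was present in them: with these features kept, 420 were tested with the limma test, 48 were higher and 55 lower with DMKG. BCYRN1, at the top of the lower ones by size among the 30 with the smallest adjusted p, was at 4.40 and 5.37 FPKM untreated and 0.841 and 0.177 FPKM treated. MIR6787, with the smallest adjusted p, was at 0.503 and 0.495 FPKM untreated and 3.72 and 4.70 FPKM treated. Both were chosen after their values were seen.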

How the results depend on the processing

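None of the 3776 called genes was called in the opposite direction in any setting, and of 129 named genes with a call that were tested in every planned setting with all samples, 112 kept it in each. Counts of genes higher against lower were 2364 against 2270 with the length trend removed and 1756 against 1491 with median centring, and 1442 were lower with no filter on low values. Differing by at least 1 on the log2 scale were 302 genes higher and 216 lower with a pseudocount of 0.1, 93 and 17 with 5, and 321 and 236 with voom; 57 were lower by as much with a minimum mean of 5 FPKM, 200 after rescaling to TPM and 59 with the GC trend removed. A larger pseudocount shrinks log2 fold changes of low genes by construction; why the other settings moved these counts was not tested. Leaving out 1 sample gave 725 (without DMKG replicate 1) to 2140 (without untreated replicate 1) genes higher, 1210 (without DMKG replicate 1) to 3347 (without untreated replicate 1) lower, 190 to 228 higher and 89 to 141 lower by at least 1 on the log2 scale, and 6 to 11 lists up and 4 to 6 down; the lone sample is then assumed to vary like the other group. Lists called were 0 up and 0 down with an estimated correlation, 8 down with fry (each list against no change), and 3 down with a minimum mean of 5 FPKM. For the list of cytosolic ribosomal proteins, the median turned from 0.17 to −0.0468 under quantile normalization. The labels do not say whether equal replicate numbers mark a shared batch. Deviations of same-numbered samples correlated at r = 0.38 across genes. The log2 difference of replicate 1 minus replicate 2 was related to gene length in both groups (Spearman's rho −0.553 untreated, −0.427 DMKG). A shared batch therefore stays open. With the replicate block in the limma fit, 2280 genes were higher and 4239 lower. TET3 (adjusted p = 0.0121) was among the lower and IDH2 (0.0118) among the higher. The counts were 3289 higher and 3302 lower with the length trend removed too. Keeping transcripts apart was not run, since 0 symbols repeat. At this depth genes near 0 in a group, such as CA9, rest on few reads.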

Other observations

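Some genes of lists not described above rose or fell, although these lists did not pass camera. Among immediate early genes, KLF2 rose from 17.4 ± 1.65 to 50.1 ± 3.39 FPKM (SD, n = 2 per group) and DUSP1 from 9.42 ± 0.228 to 26.4 ± 1.27 FPKM; that list had 5 of 24 genes higher and 3 lower, also adjusted over the list alone (median −0.02, mean 0.11, camera upward with adjusted p = 0.228). In the metallothionein and zinc export list (1 of 9 higher, 4 lower; 5 lower adjusted over the list alone; camera adjusted p = 0.526), the zinc exporter gene SLC30A1 was 2.59-fold lower and MT1E 2.36-fold lower, while MT3 went from 4 reads in the untreated samples to 99 in the treated ones, a ratio of 25.8 scaled to library size (exact 95% counting interval 9.75 to 96.4). Among TGF-beta and YAP responsive genes 5 of 20 rose and 5 fell (6 and 5 adjusted over the list alone; median −0.07, mean 0.04, camera upward with 0.381), with TGFBI at 0.84 and ACTA2 at −0.85 on the log2 scale. The inflammatory cytokine list had 4 of 12 higher and 4 lower (5 and 4 adjusted over the list alone; 0.380), with VCAM1 5.74-fold lower and IL11 2.77-fold higher.

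Other lists fixed before the data were examined gave no list call: antigen presentation (2 of 9 higher, 2 lower, camera adjusted p = 0.600), ferroptosis and iron (5 of 20 higher, 7 lower, or 9 lower over the list alone, 0.706), apoptosis (2 of 22 higher, 5 lower, 0.381), fatty acid oxidation (5 of 25 higher, 4 lower, 0.218), homeobox genes (0 of 10 higher, 2 lower, 0.693) and glioma stem and neural progenitor markers (3 of 15 higher, 4 lower, or 5 lower over the list alone, 0.648). Median and mean differed in sign, with camera upward, for antigen presentation (0.02 and −0.04), ferroptosis (−0.05 and 0.06) and the glioma stem list (0.08 and −0.01). In the last of these L1CAM rose 6.24-fold from a low level, while SOX2 was 1.85-fold lower and SOX11 1.82-fold lower. NOTCH3 rose 3.51-fold and the adhesion gene MCAM fell from 70.8 ± 4.13 to 28.7 ± 0.101 FPKM. When genes were grouped by symbol prefix after the data were seen (84 families of at least 15 genes), camera called 2 families up (LINC, 19 of 94 higher and 7 lower, and RPL, 0 of 60 higher and 2 lower) and 5 down (KIF, NUP, CEP, DDX and CDC). The kinesins (KIF) had 16 of 30 genes lower and the nucleoporins (NUP) 13 of 23, with camera adjusted p = 8.40e-05 and 0.0162, and adjusted p = 0.905 with an estimated correlation for all 7 families; with the GC trend removed 16 and 6 were lower.

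Of the tests below, those of scaling, ATF4 targets, the share of cycling cells, shared reads, ribosomal proteins and the GC trend were chosen after the results were seen.

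The rise of all 35 hypoxia and HIF targets stands out for its direction. 2-oxoglutarate is a substrate of the prolyl hydroxylases that mark HIF for degradation. More substrate alone would point to a fall of HIF targets, not a rise. A length or GC trend between libraries is argued against by the 35 genes still higher with either trend removed. Centring each library on its own median moves all its genes alike, so the list median of 1.98 is no separate test of scaling. As deposited, the list median already lay 1.98 above that of all genes, a gap that a shared factor would not produce. A general ATF4 stress response as the source is argued against by the 19.4% of ATF4 targets outside the hypoxia list that were higher (7 of 36, with 14 lower). HIF1A mRNA was not called higher in any setting, and EPAS1 (HIF-2 alpha), like HIF1A looked up after the result was seen, was at 15.6 ± 1.12 and 14.3 ± 1.18 FPKM, so a hypothesis is that DMKG or a product of it may act on HIF protein or hydroxylase activity, which these data do not measure. Lower oxygen in the treated cultures stays open as well, as the labels do not give culture oxygen or density.

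The fall of 39 of 40 G2/M genes was also kept with the length or the GC trend removed (39 genes in both). If fewer cycling cells were the whole cause and both lists depended equally on cycling, DNA replication genes would be expected to fall as much. The replication median lay 0.77 above the mitosis median on the log2 scale (95% bootstrap interval 0.65 to 0.91 over genes, which are not independent). How far each list depends on cycling was not measured, so this gap cannot decide whether fewer cycling cells were the cause. A lower share of cycling cells or a shift in the distribution of cells over the cycle stays open. Another hypothesis is a direct effect on mitotic gene transcription, for example through the CDKN1A rise. None of these was measured here.

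RPS18 and NAP1L4, each listed at more than 1 locus, were among the largest falls. Reads shared between copies of a locus may contribute. Of 444 tested genes with more than 1 locus, 9.91% differed at least 2-fold between the samples of a group. The rate was 0.150% for genes with 1 locus matched on mean FPKM. These rates describe spread within a group, so they cannot decide the cause of a difference between groups. NAP1L4 had such a spread, with 4.39 and 17.3 FPKM in the treated samples. RPS18 did not, at 406 and 342 FPKM untreated and 143 and 99.9 FPKM treated. Of the 444 genes 109 were called, against 30.6% of all tested genes. A fall of ribosomal protein transcripts in general is argued against for RPS18, since 0 of the 59 other ribosomal protein genes were lower as deposited, and under quantile normalization, where 13 were lower, the largest fall among them was −0.32 on the log2 scale against −1.71 for RPS18. A change specific to these genes stays open. GAPDH, PGK1 and GPI rose among the reference genes, which a follow-up by qPCR would need to take into account.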
